A study of Mus musculus with 2 samples.

How the data were processed

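Cells were dissociated with a collagenase from the periodontal ligament of extracted CD1 mouse teeth, and 2 libraries were made with droplet-based 3′ single-cell chemistry, per the labels' protocols. The periodontal ligament is the connective tissue that anchors the tooth root in its socket. Both libraries carry the same label, homeostasis, and differ only in their replicate number. Nothing in the labels says that they came from separate animals. With the library as a block, p-values rest on how class differences vary between these libraries, which may be technical. That variation was pooled over all classes of a fit and moderated across genes. It is therefore not the spread of the compared classes alone. Per the file headers, the barcodes of library 1 carry a prefix with the words sham and control, and those of library 2 a code. The labels put both in 1 group, and they were treated so.

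Cell Ranger, Seurat and the mouse build GRCm38 are named, without versions, per the submitters' processing notes. The filters on barcodes and genes are not given in the sources used here. The deposited values are whole numbers per gene and barcode, used here as a score without a stated unit, and what the authors did to make them from reads is not given in the sources used here. They were first recorded as counts of molecules. Their scatter was examined before any classes were compared, and the recorded unit was changed to score after the first limma fit had been made. For a gene with a summed value from 3 to 9 in a pair of most similar cells, the squared difference was 0.348 times that of counting in library 1 and 0.267 times in library 2. Raw counts would give 1 or more on average. Pairs were found on a random part of the genes and tested on the rest. The same measure on Poisson draws around the deposited values gave 2.28 and 1.87. The tests had been planned on counts with a count model. No count model was run, and limma took its place. If values were smoothed over cells or genes they share information, so the spread between libraries can be too small and the genes left out of clustering are not fully independent of it.

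Cells were kept with at least 200 genes above 0 and at most 20% of the total in mitochondrial genes. Simulated doublets, 2 per cell, were embedded with the cells of each library, and the cells with most simulated neighbours were removed at a rate of 0.8% per 1000 cells. That removed 8 of 1002 cells in library 1 and 9 of 1051 in library 2, and left 994 and 1042. The median total per kept cell was 5859 in library 1, over a range from 403 to 80403, and 7325 in library 2, over a range from 271 to 57934. Because the unit is not counts, these totals set no counting error.

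Gene lists, cell type markers and the rule for naming genes were fixed before the data were examined. There were 173 markers of 20 cell types, and 467 genes in 20 lists that were kept out of clustering. Genes of the lists can still move with the markers, so list results are not independent of how a class was named. Clustering used the log of the value per 10000, 2000 variable genes scaled within each library, 30 principal components, 20 neighbours and Leiden communities at resolution 1 (igraph 0.11.9, leidenalg 0.10.2). A cluster was named when at least 40% and at least 3 of a type's markers were raised by a log2 fold of 1 at 20 ppm or more, with a lead of 15 percentage points over the next type and no other type ahead among its 10 leading genes. Unnamed clusters of 30 cells or more were split once more. This scoring rule, the pseudocount and the size of the level filter were set after the data were seen and before classes were compared. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error of cells only.

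Levels are means over the cells of a class of each cell's values scaled to a total of 1000000 (ppm). Classes with at least 10 cells in each library entered a fit. Genes with 10 ppm or more in at least 2 of the columns were tested with limma 3.58.1 (R 4.3.3) on log2(value in ppm + 10), with the library as a block, because the classes come from the same libraries. Folds are on that scale, which understates the change of low genes. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p below 0.05. Counts adjusted over the list alone stand beside them. Lists were tested with limma's fry, adjusted over lists and comparisons. Fry's directional test asks whether a list's genes move on balance one way and does not compare a list with other genes. Lists were called by it. A list not called can still differ in both directions, which fry's mixed p tests. On simulated data for fibroblast-like cells against the other classes, with 10433 genes, the fit recovered 17.9% of genes changed by a log2 fold of 1, 76.1% at 2 and 97.0% at 3, and 3.05% of its calls were false. The simulation changed 67, 67 and 66 genes at these folds, in 1 class. Its noise was independent and equal in size for every class. These figures therefore do not give the share of false calls in the comparisons reported here.

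Genes named in the text are genes of the fixed lists with an adjusted p below 0.05, the same sign in each library and 20 ppm or more on the higher side. For fibroblast-like cells the 12 highest and 12 lowest folds were taken. For every other class, and for mural-like against fibroblast-like cells, the 8 highest and 3 lowest were taken. For tests over several types the 10 smallest p were taken. Every gene of the proposed progenitor list is also given. Where a comparison had no test, the 12 highest and 12 lowest differences were taken at the same level minimum. List medians were then set against 10000 random lists of the same size and matched level.

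Alternatives covered resolution, variable genes, scaling, doublets, cell filters, the genes kept out of clustering, the low-value filter, the block, cells per class and the fit to only the compared classes. Pseudocounts of 1 and 50, summed values, quantile normalization and median scaling were added after the data were seen. Count-based normalizations, a second count model and shares of cells after thinning to equal depth had been planned and were not run, because the values are not counts. Gene positions are from GENCODE on GRCm38. Of 22597 gene names in the files, 213 were not found in that annotation. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.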

Results

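The data are 2 single-cell RNA libraries of mouse periodontal ligament, replicates of 1 group labelled homeostasis. Library 1 held 1205 barcodes with a summed value of 9795733, and library 2 held 1686 barcodes with 10382680. Filters kept 994 and 1042 cells. Of 22597 genes listed, 15022 were above 0 in library 1 and 15404 in library 2. The labels define no treatment contrast, so the comparisons are between classes of the dissociated cells and between the 2 libraries. Some of these cells carried genes known from bone marrow, given below, and where cells sat in the tissue was not measured. Levels are mean values after each cell was scaled to a total of 1000000 (ppm).

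**Figure D1:**
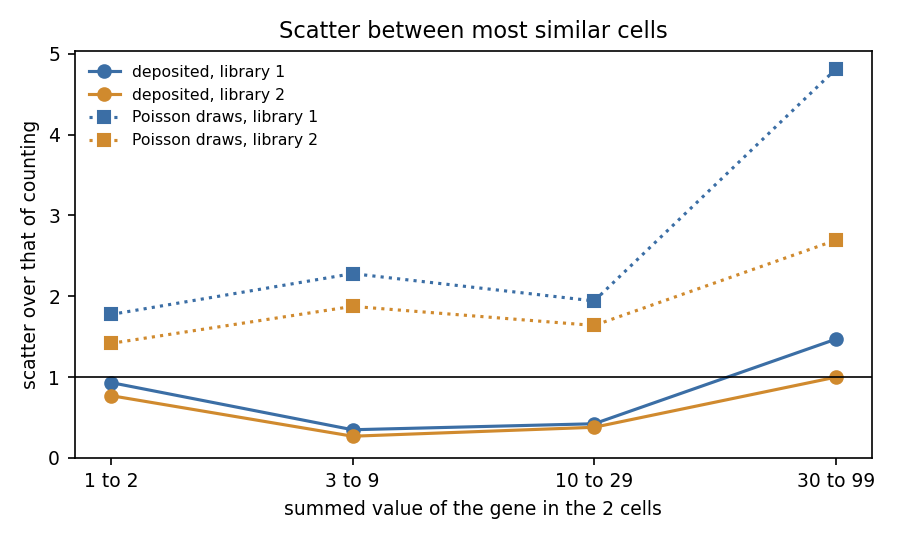
Squared difference between most similar cells over that of counting (vertical axis) by the summed value of a gene in the 2 cells (horizontal axis), for deposited values and Poisson draws around them in each library. At sums from 3 to 9 the deposited values lie at 0.348 and 0.267, under the line at 1 that counting sets, and the draws at 2.28 and 1.87, while at sums from 30 to 99 the deposited values lie at 1.47 and 0.999.

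Leukocyte-like cells were the most frequent class in both libraries, at 65.1% of cells in library 1 (95% interval 62.0 to 68.1) and 29.5% in library 2 (26.7 to 32.3). Fibroblast-like cells made up 13.4% (11.3 to 15.7) and 26.7% (24.0 to 29.5). Endothelial-like cells made up 8.65% (6.98 to 10.6) and 13.6% (11.6 to 15.9). Mural-like cells, named from markers of the pericytes and smooth muscle of vessel walls, made up 2.82% (1.88 to 4.05) and 7.97% (6.39 to 9.78). Fibroblast markers were also high in this class, as given below, and whether it holds mural cells or fibroblasts was not settled. Mineralising-like cells, with markers of osteoblasts and cementoblasts, were 8.35% of library 2 (6.74 to 10.2). Library 1 had 0 of 994 cells so named (0 to 0.370). That interval does not cover such cells clustered under another name. Fibroblast-like cells also carried the naming marker Ibsp, with more in library 1 than in library 2 (levels given below). Epithelial-like cells were 1.82% of library 2 (1.10 to 2.83) and also 0 of 994 in library 1.

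Within the leukocytes, neutrophil-like cells were 39.4% of library 1 (36.4 to 42.6) and 18.4% of library 2 (16.1 to 20.9), and macrophage or monocyte-like cells 7.34% (5.80 to 9.15) and 8.06% (6.48 to 9.88). T or NK-like cells were 5.43% of library 1 (4.11 to 7.03) and 0 of 1042 in library 2 (0 to 0.353). That interval is no limit on T cells. In library 2, 9 and 21 cells lay in 2 unnamed clusters with markers of both T and B cells. These clusters raised 8 and 6 of 10 T or NK markers. B or plasma-like cells were 7.24% (5.71 to 9.04) and 1.82% (1.10 to 2.83), and granulocyte progenitor-like cells 5.63% (4.28 to 7.25) and 1.15% (0.596 to 2.00). Over the 2 libraries the mean leukocyte share was 47.3% ± 25.2 (SD, n = 2) and the mean fibroblast share 20.03% ± 9.40 (SD, n = 2). An erythroid-like cluster of low totals, which also held mast cell and plasma cell genes, was 6.34% (4.90 to 8.04) and 7.58% (6.05 to 9.36), and 3.72% (2.63 to 5.09) and 4.51% (3.33 to 5.95) of cells stayed unnamed. Different clusters held the fibroblast-like cells of the 2 libraries, cluster 6 in library 1 and cluster 1 in library 2, and the endothelial-like cells likewise, cluster 13 and cluster 3. Neutrophil-like cells were mostly in clusters 2, 8 and 9 in library 1 and in cluster 5 in library 2, and macrophage or monocyte-like cells in cluster 14 and cluster 11.

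**Figure D2:**
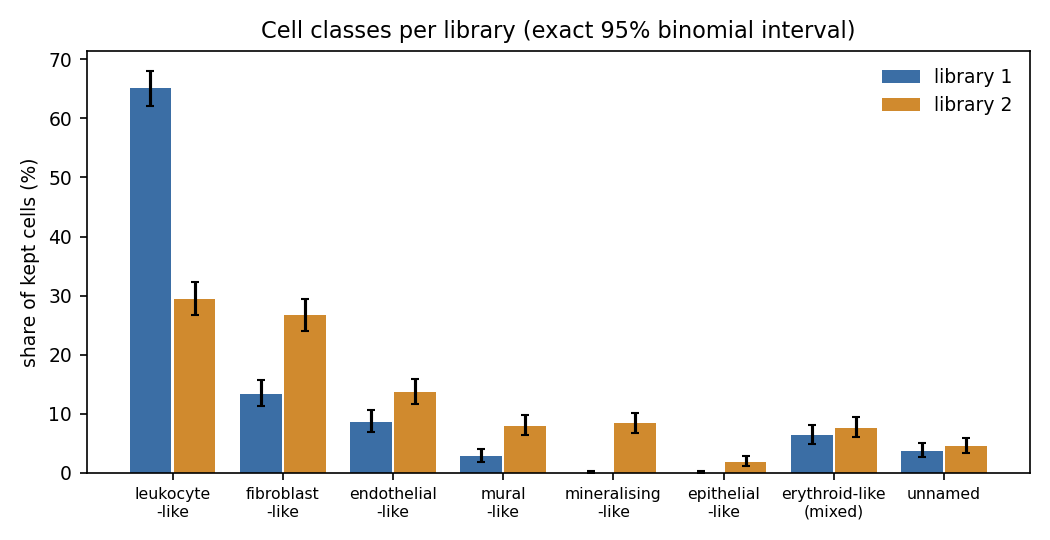
Share of kept cells (%, vertical axis) in each cell class (horizontal axis) for library 1 and library 2, with exact 95% binomial intervals as bars. The leukocyte-like bars stand at 65.1% and 29.5%, and the mineralising-like and epithelial-like classes have cells in library 2 alone.

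Fibroblast-like cells were compared with the mean of endothelial-like, leukocyte-like and mural-like cells, to find matrix and signalling genes that differ from those 3 classes. Mineralising-like cells, found in library 2 alone, were not in this comparison. The highest folds were those of Col12a1, a collagen on the surface of type I fibrils, at a log2 fold of 5.69 (SE 0.38, adjusted p = 8.35e-07), and of Omd, a mineral-binding proteoglycan, at 5.60. Wif1, a secreted Wnt inhibitor, stood at 5.57, Col11a1 at 5.52 and Thbs4 at 5.46 (6.46 in library 1 alone and 4.45 in library 2 alone). Col12a1 lies on chromosome 9 from 79598991 to 79718831 (GRCm38, protein coding). Its level was 1143 ppm in fibroblast-like cells of library 1 and 2375 in library 2. In leukocyte-like cells it was 1.76 and 1.69, in mural-like cells 97.7 and 570 and in mineralising-like cells of library 2 852. Some of the named genes were also high in other classes. In mineralising-like cells Thbs4 was at 4884 ppm, Sfrp2 at 3405, Omd at 1993 and Wif1 at 1991. In fibroblast-like cells of library 2 they were at 1039, 1203, 1868 and 2859. In mural-like cells of library 2 Sfrp2 was at 1357 and Wif1 at 2696.

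Of 44 measured genes for collagen and elastic fibre assembly, 34 were higher in fibroblast-like cells and 1 lower, with a list median log2 fold of 2.49 (fry, adjusted p = 0.00139). The class was named from collagen and other matrix markers, so this rise is not independent of its naming. Besides Col12a1, Col11a1 and Thbs4, the named members were Col5a2 (5.18), Col5a1 (4.91), Bgn (4.76) and Pcolce (4.86), the enhancer of procollagen cleavage. Of 20 genes for matrix degradation and its inhibitors, 16 were higher and 2 lower (fry, adjusted p = 5.86e-05), led by the gelatinase Mmp2 at 5.31. In the Wnt list 17 of 32 were higher and 1 lower (fry, adjusted p = 0.00227). Wif1 and Sfrp2 (4.82), which bind Wnt ligands outside the cell, were the named members. The phosphate and mineral list had 10 of 19 higher and 1 lower, among them Alpl, the tissue-nonspecific alkaline phosphatase, at 4.58. Hedgehog genes (4 of 8 higher), BMP genes (11 of 27) and axon-guidance genes (11 of 18) also rose as lists, with adjusted p of 0.00187, 0.00737 and 0.000677. In fibroblast-like cells TGF-beta genes (6 of 20 higher and 1 lower), FGF genes (5 of 16 higher and 1 lower) and mechanosensing genes (6 of 20 higher and 1 lower) rose as well, with adjusted p of 0.0189, 0.00533 and 0.0426. The mechanosensing call was lost under 5 of 15 alternatives (highest adjusted p = 0.081, without the library block) and the TGF-beta call with a pseudocount of 50 (adjusted p = 0.0623). The other side includes leukocyte-like cells, where TGF-beta, FGF and mechanosensing lists fell. There 11 of 20, 12 of 16 and 15 of 20 members were lower, and 2, 0 and 1 higher. The rises in fibroblast-like cells are thus partly against those low levels. The median log2 fold of the FGF list was 0.32 in fibroblast-like and 0.76 in mural-like cells. That of the mechanosensing list was 0.57 in fibroblast-like and 0.63 in endothelial-like cells (not called). Several of the lists that rose in fibroblast-like cells also rose in mural-like cells against the mean of the other classes. They were the hedgehog (4 of 8), BMP (14 of 27) and axon-guidance lists (7 of 18), with adjusted p of 0.00464, 0.00344 and 0.00113, and the phosphate and mineral (10 of 19) and TGF-beta lists (9 of 20), with 0.0249 and 0.0179. The TGF-beta call in mural-like cells was also lost with a pseudocount of 50 (fry, adjusted p = 0.0503). Between mural-like and fibroblast-like cells these 5 lists were not called (0.11, 0.116, 0.178, 0.792 and 0.828). Fry's mixed p, which allows both directions, gave adjusted values of 0.00998, 0.0185, 0.0883, 0.0394 and 0.118 for them. The mechanosensing list, with 3 of 20 higher, was not called in mural-like cells (0.134). Basement membrane, angiogenic, cell cycle and immediate-early lists were not called (adjusted p of 0.196, 0.688, 0.244 and 0.244). The list of signals to osteoclasts was not called either (0.0675), with a rise by test and a median of −0.09, which was −0.09 in library 1 alone and 0.10 in library 2 alone. By fry's mixed p some of these lists did differ in fibroblast-like cells. Adjusted values were 0.00029 for basement membrane (5 higher and 6 lower of 18) and 0.00317 for angiogenic genes (4 and 4 of 18). They were 0.01 for immediate-early genes (1 and 9 of 25), 0.00266 for signals to osteoclasts and 0.226 for cell cycle.

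The lowest folds belonged to leukocyte and endothelial genes. The chemokine Cxcl2 stood at −4.42, the invariant chain Cd74 at −4.18, Il1b at −3.80 and its antagonist Il1rn at −3.06. Cd34, an endothelial gene here, followed at −2.67, then Ccl4 at −2.65 (−1.72 in library 1 alone and −3.57 in library 2 alone), H2-Eb1 of MHC class II at −2.39 and Ccl3 at −2.30. H2-Ab1, H2-Aa, Tnf and Ccl6, also among the 12 lowest, were listed at 0 in fibroblast-like cells of both libraries and are given no fold. As lists, cytokine genes fell with 16 of 30 members (adjusted p = 0.00177), Notch genes with 6 of 15 (0.00562) and MHC class II genes with 5 of 10 (0.0342). The MHC class II call was lost under 6 of 15 alternatives (adjusted p up to 0.117). The proposed progenitor list rose with 7 of 18 members and 2 lower (0.00047). It fell in leukocyte-like cells, with 16 of 18 lower (fry, adjusted p = 6.71e-05). Its median log2 fold was 0.43 in fibroblast-like and 1.77 in mural-like cells. In all, 138 of 388 tested genes of the lists were higher and 57 lower, and 153 and 81 adjusted over the list alone. Without the filter on low values 30 were lower. Library 1 fibroblast-like cells had raised levels of 7 of the 12 mural markers against the rest of that library.

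**Figure D3:**
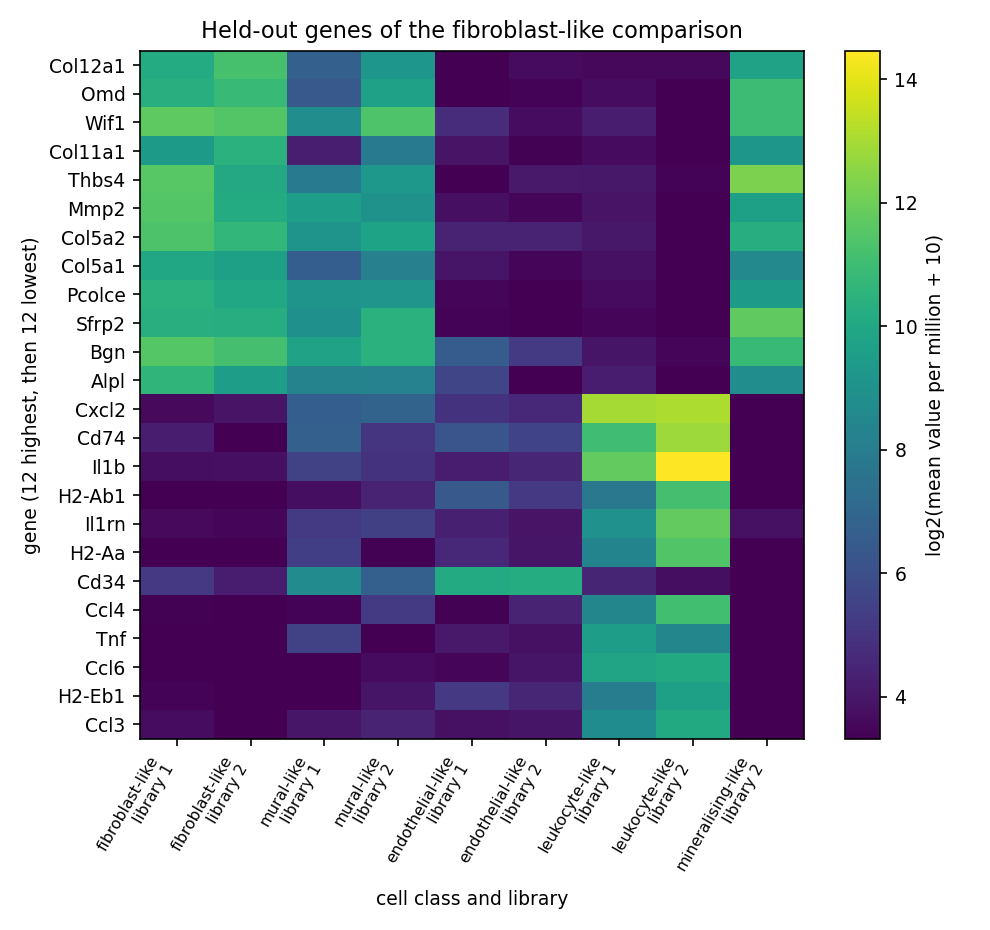
Levels as log2(mean value in ppm + 10), by colour, of the 12 highest and 12 lowest genes of the fibroblast-like comparison (vertical axis) in each cell class and library (horizontal axis). Col12a1 reads 1143 and 2375 ppm in fibroblast-like cells, against 1.76 and 1.69 in leukocyte-like cells.

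Mineralising-like cells were compared with fibroblast-like cells in library 2 alone, because library 1 held none, and no test was possible. Both classes come from 1 library, 87 and 278 cells, so the differences have no replicate check. The highest was Bmp8a, a BMP ligand, at 315 ppm against 7.36 (log2 difference 4.23). Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin, stood at 388 against 15.6 (3.96). Ank, a pyrophosphate transporter, stood at 687 against 40.3 (3.79), and Enpp1, which makes pyrophosphate, at 268 against 18.3 (3.30). Cdh2 (2.87), the secretory kinase Fam20c (2.71), Sema3d (2.65), Tcf7 (2.59), Fgf9 (2.43), Pthlh (2.37), Unc5b (2.23) and Thbs4 (2.22) completed the 12 highest.

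The lowest was Mgp, matrix Gla protein, an inhibitor of calcification, at 10.99 ppm in mineralising-like and 1154 in fibroblast-like cells (log2 difference −5.79). Thbs2 (−4.21), Cxcl1 (−3.00), Fgf7 (−2.95), Fmod (−2.85) and Adamts1 (−2.84) followed, then Col4a1 (−2.63), Col4a2 (−2.53), Col6a3 (−2.42), Fbln5 (−2.40), Icam1 (−2.32) and Cxcl14 (−2.27). Of 277 genes of the lists, 44 were higher and 82 lower by a log2 difference of 1 or more. The phosphate and mineral list had 8 of 18 higher and 1 lower, and its median of 0.75 lay above all of 10000 random lists. The class was named from mineralisation markers, so this rank is not independent of its naming. Random lists drew genes singly and do not match genes that move together, so percentiles here are not p-values. The FGF list, with 6 of 13 higher, 2 lower and a median of 0.70, lay at percentile 99.99. The list of signals to osteoclasts had 3 of 7 higher and 1 lower and lay at percentile 99.9. Lists for collagen assembly (15 of 41 lower), matrix degradation (8 of 18), basement membrane (6 of 12), angiogenic signals (6 of 12) and cytokines (9 of 11) had medians of −0.45, −0.90, −0.87, −1.06 and −1.94, below all random lists. The immediate-early list, genes that tissue dissociation also induces, had 16 of 24 lower and a median of −1.36. The proposed progenitor and mechanosensing lists lay at percentiles 1.08 and 0.8, with medians of −0.36 and −0.34. The bone sialoprotein gene Ibsp, a naming marker, was at 25561 ppm in mineralising-like cells, and at 1879 and 433 in fibroblast-like cells of libraries 1 and 2. With a pseudocount of 50, 23 genes were higher and 50 lower by that size.

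Mural-like cells against the mean of the other classes had their highest folds in Gpc3 (5.10, SE 0.37, adjusted p = 4.55e-06), a glypican, Ccl11 (4.84), the eotaxin chemokine, and Mfap5 (4.24), a microfibril protein. Sfrp2 (3.97), Col6a1 (3.85), Ogn (3.77), Col14a1 (3.72) and Fbln1 (3.65) followed. Log2 folds in library 1 alone and library 2 alone were 5.72 and 4.47 for Gpc3, 5.63 and 4.06 for Ccl11, 3.15 and 4.78 for Sfrp2, 3.07 and 4.46 for Ogn, 4.32 and 3.11 for Col14a1 and 3.05 and 4.25 for Fbln1. Gpc3 lies on chromosome X from 52272426 to 52613950 (GRCm38) and stood at 1201 and 320 ppm in the 2 libraries. The named lower genes were Ccl6 (−2.20), H2-Ab1 (−2.14) and H2-Eb1 (−2.06). Of 388 genes, 157 were higher and 8 lower (192 and 23 adjusted over the list alone), with 34 of 44 fibre assembly genes and 13 of 18 proposed progenitor markers higher. Wnt genes (14 of 32 higher) and FGF genes (6 of 16) rose as lists (adjusted p of 0.00484 and 0.00405), as they did in fibroblast-like cells. So did matrix degradation genes, with 13 of 20 higher and 1 lower (fry, adjusted p = 7.74e-05). Against all other cells of each library the class raised 10 of 12 mural markers. Rgs5, a pericyte marker, was at 766 and 845 ppm against 177 and 17.8 in fibroblast-like cells. Tagln was below fibroblast-like cells in library 1 and above them in library 2 (40.9 and 372 against 82.4 and 131). Cspg4 was at 92.3 and 31.1 against 72.2 and 22.2, and Ndufa4l2 at 45.8 and 45.7 against 41.7 and 35.2. Acta2, Myh11, Kcnj8, Abcc9, Higd1b and Mcam were also above fibroblast-like cells in both libraries. Des (3.04 and 7.76) and Cnn1 (0 and 8.76) were the lowest of the 12. The 10 leading genes of the class included the matrix genes Mfap5 and Col14a1 and the chemokine gene Ccl11. Among these 10 genes Rgs5 was the only marker of mural cells from the fixed list and Dcn the only marker of fibroblasts, at 44962 and 3367 ppm against 7493 and 2166 in fibroblast-like cells. The fibroblast markers Pi16 (569 and 37.8 ppm against 33.8 and 0.917), Clec3b (406 and 35.4 against 19.4 and 4.99) and Dpt (127 and 96.7 against 72.6 and 77.8) were also above fibroblast-like cells in both libraries. Col1a1 (4007 and 4547 against 59985 and 39169) and Postn (157 and 844 against 3036 and 3123) were below them. The class raised 5 of 10 Schwann cell markers. Notch and osteoclast lists, called at adjusted p of 0.0169 and 0.0353, each lost the call under 8 of 14 alternatives. The median log2 fold of all genes was 0.15, and −0.05 with quantile normalization. At resolution 0.5 no mural-like class was named, and without the filter on low values 74 genes were higher.

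Mural-like cells were also set against fibroblast-like cells directly. The name mural-like rests on the markers given above, and the position of these cells in the tissue was not measured. Since some fibroblast markers were higher in this class, the differences may be between kinds of fibroblasts. Ccl11 (log2 fold 4.74, SE 0.48, adjusted p = 0.000686), Gpc3 (3.52), Il33 (3.44), Col14a1 (3.34), Mfap5 (3.34), Tgfbi (3.19), Cd34 (3.05) and Cxcl2 (2.99) were higher in mural-like cells. Col11a1 (−3.85), Col12a1 (−2.73) and Thbs2 (−2.41) were lower. Il33 stood at 511 ppm in library 1 and 22.0 in library 2. Log2 folds in library 1 alone and library 2 alone were 5.28 and 1.60 for Il33, 4.48 and 1.90 for Tgfbi, 5.63 and 3.85 for Ccl11, −5.16 and −2.55 for Col11a1 and −3.42 and −2.04 for Col12a1. The Notch list rose (2 of 15 called, median 1.04, adjusted p = 0.00818), as did basement membrane (3 of 18, adjusted p = 0.00344) and cytokine genes (5 of 30, adjusted p = 0.00446). Endothelial markers were also above fibroblast-like cells, with Pecam1 at 56.3 and 27.7 ppm against 3.57 and 4.52, Cdh5 at 58.8 and 24.1 against 1.41 and 1.13 and Flt1 at 72.0 and 13.3 against 1.48 and 0.275. In endothelial-like cells Pecam1 was at 1923 and 1870 and Cd34 at 1097 and 1182, and in leukocyte-like cells Cxcl2 was at 7997 and 8706. Matrix degradation genes fell (3 of 20, median −0.49, adjusted p = 0.000607). That call was lost at resolution 2.0 (0.077), and the Notch call with genes scaled over both libraries (0.066) and under the stricter cell filter. Fibre assembly genes, with 5 higher and 9 lower of 44, were not called as a list (0.191). In all, 25 genes were higher and 16 lower (53 and 36 adjusted over the list alone). It was 21 and 28 with median scaling, 20 and 19 with quantile normalization, and 10 and 1 without the library block. Without the filter on low values it was 0 and 0 by limma, with 76 and 50 at an unadjusted p under 0.05. Median log2 folds of all genes were 0.13 before and −0.03 after median scaling. Fibroblast-like cells of library 1 had themselves raised 7 of the 12 mural markers, and Rgs5 stood at 177 ppm in them and 17.8 in those of library 2.

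Markers proposed for ligament progenitors are given as mean ± SD (n = 2) for fibroblast-like and mural-like cells and as the level of library 2 for mineralising-like cells. The list was higher in mural-like than in fibroblast-like cells (3 of 18 called, median 0.24, adjusted p = 0.00198; median 0.41 in library 1 alone and 0.30 in library 2 alone), but not at resolution 2.0 (adjusted p = 0.122, the highest over 14 alternatives) or with median scaling. Gli1, a hedgehog target used to trace ligament stem cells, was at 26.6 and 7.31 ppm in fibroblast-like cells of libraries 1 and 2, 94.1 and 17.7 in mural-like cells and 6.21 in mineralising-like cells. Axin2, a Wnt target, was at 21.4 ± 0.303 in fibroblast-like, 29.6 ± 0.859 in mural-like and 29.2 in mineralising-like cells. Cd34 was at 16.9 ± 12.6 in fibroblast-like and 252 ± 222 in mural-like cells and listed at 0 in mineralising-like cells. Sox9 was at 27.9 ± 2.72, 157 ± 40.7 and 19.4, and the leptin receptor Lepr at 18.2 ± 8.67, 102 ± 59.0 and 4.82. Thy1 was at 6.80 ± 3.07, 58.2 ± 9.97 and 0.402, Ly6a at 126 ± 31.8, 406 ± 283 and 83.3, and Grem1 at 37.1 ± 8.31, 66.9 ± 23.9 and 1.12.

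Among the other members, Ctsk, which encodes cathepsin K, was at 668 ± 16.2 ppm in fibroblast-like, 264 ± 78.8 in mural-like and 361 in mineralising-like cells. Prrx1, a mesenchyme transcription factor, was at 504 ± 91.7, 439 ± 39.97 and 134, Pdgfra at 214 ± 71.5, 224 ± 22.7 and 215, and Pdgfrb at 227 ± 23.4, 207 ± 77.0 and 107. Msx1 was at 195 ± 64.4, 224 ± 104 and 84.3, Eng at 55.4 ± 1.33, 54.2 ± 15.9 and 64.5, and Itgav at 29.8 ± 2.66, 53.5 ± 9.54 and 31.4. Cd200 was at 145 ± 13.0, 123 ± 73.0 and 439, Wnt10a at 60.4 ± 9.06, 30.1 ± 35.9 and 168, and Nt5e at 43.7 ± 1.03, 48.0 ± 23.6 and 85.2. Msx2 was at 2.09 ± 2.95, 5.98 ± 8.46 and 9.65, Lgr5 at 0.775 ± 1.10, 0.864 ± 0.114 and 1.45, and Lrig1 at 0.871 ± 0.525, 0.896 ± 1.27 and 0.855. In endothelial-like cells Ly6a was at 1893 ± 45.9, Cd34 at 1139.5 ± 59.5, Cd200 at 910.4 ± 0.886 and Eng at 719 ± 18.3, each above its level in fibroblast-like, mural-like and mineralising-like cells. Lepr was at 107 ± 26.6, which differed from mural-like cells by less than the spread between libraries. In leukocyte-like cells Gli1 was listed at 0, Axin2 was at 0.343 ± 0.486 and Lgr5 at 1.28 ± 0.926. Other members were higher there, with Ly6a at 37.9 in library 1 and 10.9 in library 2, Nt5e at 18.1 ± 4.14, Itgav at 17.8 ± 0.837, Ctsk at 8.54 ± 3.09 and Cd34 at 7.96 ± 6.39. Thy1 was at 7.10 ± 7.17, against 6.80 ± 3.07 in fibroblast-like cells.

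Endothelial-like cells had their highest folds in Cd34 (4.67, SE 0.33, adjusted p = 6.94e-07), Tek (4.43), the angiopoietin receptor, and Hspb1 (4.41). Col4a1 (4.33), Itga6 (4.25), Eng (4.17), Ly6a (4.04) and Col4a2 (4.01) followed. Sfrp2 (−4.42), Mmp2 (−4.30) and Wif1 (−4.27) were lowest. Log2 folds in library 1 alone and library 2 alone were 3.99 and 5.34 for Cd34 and −3.49 and −5.05 for Wif1. Basement membrane genes rose with 16 of 18 members (median 1.82, adjusted p = 0.000451), Notch genes with 9 of 15 (adjusted p = 0.00187) and angiogenic genes with 10 of 18 (adjusted p = 0.00535). Fibre assembly genes fell with 32 of 44. The proposed progenitor list had 9 members lower and 5 higher, among them Cd34, Ly6a and Eng (adjusted p = 0.0176 for a fall). That call was lost under 8 of 15 alternatives, with adjusted p up to 0.702. At resolution 0.5 the test gave a rise (adjusted p = 0.00501) while the median was −0.67, so median and test differed in sign. The median log2 fold of all genes was 0.16, and −0.12 with median scaling. In all 83 genes were higher and 119 lower (88 and 139 adjusted over the list alone).

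Leukocyte-like cells had their highest folds in Il1b (8.67, SE 0.45, adjusted p = 2.64e-08), Cxcl2 (7.94), Cd74 (6.76), Ccl6 (6.45), Il1rn (6.05), H2-Aa (5.90), Ccl4 (5.89) and Ccl3 (5.55). In library 1 alone and library 2 alone the log2 folds were 7.30 and 10.03 for Il1b, 5.32 and 8.20 for Cd74, 4.59 and 7.51 for Il1rn, 3.91 and 7.90 for H2-Aa, 5.04 and 6.75 for Ccl4 and 4.91 and 6.19 for Ccl3. Mgp (−6.31), Serpinh1 (−6.12), the collagen chaperone, and Timp3 (−5.41) were lowest. All 10 measured MHC class II genes were higher, 17 of 30 cytokine genes and 19 of 23 cell cycle genes, with adjusted p of 0.0054, 0.0009 and 0.0497. The cell cycle call was lost under 7 of 15 alternatives (adjusted p up to 0.115). The median log2 fold of that list was 2.5 in library 1 alone and 0.988 in library 2 alone. The immediate-early list was not called (0.177). Wnt, BMP, hedgehog and axon-guidance lists fell, with 23 of 32, 20 of 27, 8 of 8 and 11 of 18 members lower. Their adjusted p by fry were 0.00198, 0.00125, 0.00131 and 0.000386. In all 58 genes were higher and 244 lower (66 and 262 adjusted over the list alone). The median log2 fold of all genes in this comparison was −0.48, and −0.11 with median scaling, so lower calls stand against that shift.

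The 4 leukocyte types with enough cells in both libraries were neutrophil-like, macrophage or monocyte-like, granulocyte progenitor-like and B or plasma-like cells. Of 174 tested genes of the lists, 118 differed among them (128 adjusted over the list alone). The smallest p belonged to Ccl6 (adjusted p = 2.86e-06), at 1395 and 1536 ppm in neutrophil-like cells and 564 and 379 in macrophage or monocyte-like cells. Cxcl2 and Il1rn were likewise highest in neutrophil-like cells, while Il1b was at 4293 and 34615 ppm in them and at 7845 and 3158 in macrophage or monocyte-like cells. Lef1, a Wnt-pathway transcription factor, was at 413 and 444 in B or plasma-like cells. H2-Aa, H2-Ab1, H2-Eb1, Tgfbi and Fn1 were highest in macrophage or monocyte-like cells. Cell cycle genes differed in 24 of 25, cytokine genes in 22 of 23 and MHC class II genes in 13 of 13. With at least 20 cells per type the count was 77 of 148 tested genes. In that fit 2 types were left, and what lowered the count was not tested.

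Fibroblast-like cells were clustered again without the lists and gave 5 subclusters. Among 338 genes of the lists, 60 differed (88 adjusted over the list alone), 17 of them in the fibre assembly list of 45. Col11a1 (adjusted p = 7.09e-08) was at 163 and 489 ppm in subcluster 3 and 1159 and 2781 in subcluster 5. Col12a1 followed the same order, with 391 and 1134 against 1762 and 4361. Cxcl12, a chemokine of stromal niches, was at 793 and 351 in subcluster 3 and 75.0 and 10.7 in subcluster 5, and the Notch target Hes1 at 287 and 233 against 20.1 and 18.6. Col6a1, Col6a2, Ecm1 and Gas1 were also highest in subcluster 3, and Col5a1 and Thbs2 in subcluster 5. The number of genes was 1 without the library block and 16 with 1000 variable genes.

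The 2 libraries were compared within each class, as a description, since both belong to 1 group, although their barcode prefixes differ. Pearson's r of log2 levels across genes, which are not independent replicates, was 0.905 in fibroblast-like, 0.890 in endothelial-like, 0.880 in leukocyte-like and 0.783 in mural-like cells. Levels differed by a log2 ratio of 1 or more for 768 of 8839 genes in fibroblast-like cells (cluster 6 against cluster 1) and 3019 of 9953 in mural-like cells, where library 1 held 28 cells. The fit used the same residual variance for every class, so p-values of comparisons with mural-like cells can be too small. In fibroblast-like cells Nog, a BMP antagonist, was at 137 ppm in library 1 and 23.0 in library 2, and Cxcl5 at 9.38 and 78.0. Leukocyte-like cells of the 2 libraries lay mostly in different clusters and differed in their types, with 54 T or NK-like cells in library 1 and 0 in library 2. In them Csf1 was at 27.3 and 1256, Ptgs2 at 88.0 and 1930 and Ccl5 at 401 and 7.58. The immediate-early genes Egr1 (129 and 1835) and Atf3 (128 and 1757) were also lower in library 1. These genes were the ones with the largest ratios and were chosen after their values were seen.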

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

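All tests in this part were chosen after the values were seen, and no biological explanation was tested, since the labels give 1 group.

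Data outside the comparisons held further signals. Among barcodes removed for having under 200 genes, haemoglobin genes made up at least 50% of the total in 81.25% of 48 barcodes in library 1 (95% interval 67.4 to 91.1) and 99.1% of 436 in library 2 (97.7 to 99.7). In library 1, 6 barcodes had a summed value of 50 or more over 11 genes known from olfactory sensory neurons, among them Omp, and library 2 had 0. An unnamed cluster of 18 cells, nearly all in library 2, carried both Schwann cell markers and epithelial keratins, with Krt14 at 29737 ppm in its 17 cells of library 2. In 5 barcodes of library 1, Ibsp was above 100000 ppm.

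For summed values up to 29 similar cells differed by less than counting allows, while from 30 to 99 the ratio of scatter to that of counting was 1.47 in library 1 and 0.999 in library 2. Raw counts are excluded by this ratio, 0.348 at most over both libraries for summed values from 3 to 9. A subtraction of free RNA from raw counts would keep the counting scatter, and the ratio of 0.422 at most for values from 10 to 29 argues against it. Smoothing over similar cells, or division by a large number before rounding, stays open. The lowest twentieth of pairs had a ratio of 0.0743 at most, and smoothing and division cannot be told apart from these values, because each can lower the scatter to any level.

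The 5 barcodes with Ibsp were rich in Jchain and Igkc, genes of plasma cells, and sat in the erythroid-like cluster, whose median total was 527. Their own totals were not low, since Ibsp alone ranged from 2196 to 32252 in them. Ibsp took from 20.5% to 76.8% of their totals and they held 97.9% of all Ibsp in the kept cells of library 1. A mineralising cell in the same droplet would bring Col1a1, Sparc and Bglap, whose sum was 110, or 0.0408% of the amount expected from mineralising-like cells of library 2. Values moved between cells or genes by the authors' processing may be the source and stay open, since values before that processing were not analysed here.

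S100a9, an abundant neutrophil gene, was at 11867 ppm in fibroblast-like cells of library 1 and 0 in those of library 2. RNA of neutrophils in every droplet would bring their other genes in proportion. In fibroblast-like, mural-like and endothelial-like cells of library 1 the other 9 neutrophil markers had a median of 0.0996 times the level that S100a9 calls for. S100a8 was at 234 in fibroblast-like cells where 6294 was called for. Neutrophil RNA that the authors' processing removed in part may still account for it: S100a9 stood at 6.49% of its neutrophil level in fibroblast-like, 3.63% in mural-like and 0.527% in endothelial-like cells, and values before that processing, not analysed here, would be needed to decide.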

How the results depend on the processing

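Pseudocounts of 1 and 50, summed values, quantile normalization and median scaling were alternatives chosen after the data were seen. Of 1145 values of named genes under alternatives, 1101 kept direction and call, 44 lost the call and 0 turned, 15 of the losses without the filter on low values. The 1101 include 68 values without library 1 and 68 without library 2, which had no call to keep. The naming rule had already fixed their direction. They also include 68 values with at least 20 cells per class, where the same 4 classes entered and the fit was unchanged. Of 1035 list values 924 were the same, 64 lost the call, 46 moved and 1 turned. The 924 include 62 values with at least 20 cells per class, where the fit was unchanged. They also include 40 values without library 1 and 38 without library 2, which had no test. The 46 moved values were medians with 1 library left out, 22 of 62 without library 1 and 24 of 62 without library 2. Of 286 values of the 20 genes named in tests over several types, 268 kept the call. The cause was not tested for any change here, and under some alternatives fewer types or classes entered a fit.

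Counts for mural-like against fibroblast-like cells were 25 higher and 16 lower. They were 0 and 0 by limma without the filter on low values (76 and 50 at an unadjusted p under 0.05), 49 and 43 with only the 2 classes in the fit, 12 and 2 with a pseudocount of 1, and 42 and 30 under the stricter cell filter. With 1000 variable genes they were 38 and 28. The lower count was 25 with possible doublets kept, 28 with the listed genes allowed in clustering and 28 with median scaling. Lists called down were 2 with genes scaled over both libraries and 3 with quantile normalization or median scaling, against 1.

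The library is the replicate block. Without the replicate block, mural-like against fibroblast-like cells had 10 higher and 1 lower, the subclusters 1 gene against 60, and mural-like cells 5 lower against 8. Other counts of genes stayed within 1.5 times, such as 117 higher and 39 lower in fibroblast-like cells and 53 and 227 in leukocyte-like cells. Counts of lists called down in mural-like cells did not, as given below.

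Without the filter on low values, fibroblast-like cells had 30 genes lower against 57, mural-like cells 74 higher against 157 and 2 lower, leukocyte types 44 genes against 118 and subclusters 11. Subcluster genes were 106 at resolution 0.5, 16 with 1000 variable genes, 17 with doublets kept and 32 with a pseudocount of 1. Leukocyte type genes were 61 at resolution 2.0, 76 with genes scaled over both libraries and 77 with at least 20 cells. Genes lower in mural-like cells were 5 with 1000 variable genes, 14 with genes scaled over both libraries, 1 with doublets kept, 3 and 14 with pseudocounts of 1 and 50, 17 with quantile normalization and 18 with median scaling. Lists called down in mural-like cells were 1, against 0, without the filter, without the block, at resolution 2.0, with the listed genes in clustering, with a pseudocount of 1 and with quantile normalization.

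At resolution 0.5, lists called up in endothelial-like cells were 5 against 3, and the proposed progenitor list turned by test with a median of −0.67. Its adjusted p ranged from 0.00501 to 0.702 over the alternatives. The mural-like share was 0 at resolution 0.5. The mixed erythroid-like share, 6.96%, was 1.75% at resolution 2.0, 5.54% with 1000 variable genes and 1.57% under the stricter cell filter. The unnamed share, 4.12%, was 6.51% and 6.96% at resolutions 0.5 and 2.0, 2.10% with 1000 variable genes, 5.64% with doublets kept and 7.52% under the stricter filter. The mural correlation between libraries was 0.844 from summed values. Mineralising-like against fibroblast-like counts were 23 and 50 with a pseudocount of 50.

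The median log2 fold of all genes in leukocyte-like cells was −0.48, −0.09 with quantile normalization and −0.11 with median scaling. Leaving out 1 library leaves no test, so counts of calls cannot be computed; leukocyte shares then ranged from 29.5% to 65.1%. Subclusters could not be tested with genes scaled over both libraries. Size factors of another count tool, a second count model and thinned shares of cells were not run, because the values are not counts, and scaling by library totals equals the scaling used. Depth cannot be stated for values that are not counts.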

Other observations

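The bounds of the 2 subcluster tests were written before those tests were run, on subclusters already seen in these data. That a median under the bound decides nothing where markers go both ways was applied after the values were seen. The cluster levels that follow were chosen after their values were seen.

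Both libraries held cells with genes of early granulocyte and B cell stages, which are known from bone marrow, with more of them in library 1. In library 1 a cluster of 56 cells led by Elane and Mpo, enzymes of early granules, had 5382 and 5295 ppm of them. A cluster of 106 cells led by Chil3, Camp and Ngp had Ngp at 33661 and the proliferation gene Top2a at 510. In another neutrophil-like cluster, of 181 cells, Ngp was at 2936, Cxcl2 at 21513 and Il1b at 8554. B-lineage cells of library 1 were mostly 1 cluster of 54 cells with Vpreb1 at 1769, Igll1 at 1149, both parts of the pre-B cell receptor, and Top2a at 1044. The 5 cells of library 2 in that cluster had Vpreb1 at 391 and Igll1 at 457. In library 2 the largest neutrophil-like cluster, of 136 cells, had Il1b at 47587, and smaller clusters of 23 and 12 cells had Camp among their leading genes. The cluster of 12 cells raised 5 of 5 granulocyte progenitor markers.

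Macrophage or monocyte-like cells also differed in kind. In library 1 a cluster of 68 cells had the monocyte genes Ccr2 at 852 and Ly6c2 at 857 and the complement gene C1qa at 12.4 ppm. In library 2 a cluster of 84 cells had C1qa at 1596, Ccr2 at 626 and Ly6c2 at 136. T-like cells of library 1 carried Icos at 711, Cxcr6 at 624 and Gata3 at 595. The epithelial-like cells of library 2, 19 in number, carried Krt14 at 33621, Col17a1, a hemidesmosome collagen, at 662 and Odam, a gene of junctional and enamel epithelium, at 602.

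The fibroblast-like subcluster with most Cxcl12 may be closer to mural-like cells than the other fibroblast-like cells. Its mural markers were higher by a median log2 difference of 0.93 over 8 markers in library 1 and 0.74 over 5 in library 2, above the bound of 0.5 set beforehand. In library 1, 6 of the 8 were higher, with Acta2 at −0.11 and Tagln at −0.38, and in library 2 5 of 5, with Acta2 at 1.33 and Tagln at 0.74. The markers measured differ between the libraries because of the level minimum. The markers were not kept out of that clustering, so the test is not independent of it. The subcluster with most Col12a1 was asked in the same way whether it is closer to mineralising cells. The median log2 differences of 0.29 and 0.23 lay under the bound, so the prediction written beforehand was not met. Markers went both ways, with 6 of 9 higher in library 1 and 3 of 6 in library 2. Only by the rule added afterwards does the question stay open.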
